A study of Arabidopsis thaliana with 10 samples.

How the data were processed

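Total RNA of whole seedlings was extracted with a Qiagen RNeasy kit and made into standard Illumina libraries, per the labels' protocols. Per the submitters' processing notes, the authors used FastQC, TopHat, Cufflinks and Cuffdiff with genome build TAIR10; versions, options and the gene annotation are not given in the sources used here. The deposited values are FPKM (fragments scaled to gene length and to mapped fragments), 1 file per library with 27086 loci; the file headers say only "expression", and the unit was read from the tools named in the notes and from the values. The geometric mean of FPKM over the 15476 loci above 1 in every library was 17.0 to 17.9 in all 10 libraries although the FPKM sums ranged from 792416 to 990295, and whether the authors scaled the libraries to each other is not known here. Where the authors split reads between near-identical copies or overlapping genes, or counted without strand, a value per locus can hold reads of a neighbour; 270 loci are merged entries of overlapping genes. An exact 0 in such a file can be a failed estimate, so loci at 0 in both libraries of a compared group are described as listed at 0 and given no fold. A fold is given where 1 of the 2 libraries is at 0, as for HSP17.4, PRS and SEP2 in WT, BNQ3 in atbmi1ab_strong, and SVP, CASP1 and CASP2 in atbmi1abc, and it rests partly on that 0.

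Gene names and the 3 coordinates given come from the RefSeq annotation of TAIR10.1, which matched 26177 of the 27086 loci. No library was identical to another in any of 45 pairs. Nothing in the labels says whether the 2 libraries of a genotype came from separately grown plants, so p-values measure only the spread between these libraries, which may be technical. The labels name no batch, sowing or harvest time. Chloroplast-encoded loci held 0.744% and 2.24% of the FPKM sum in the WT libraries and at most 0.24% in the others.

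The planned count model was replaced by its fallback, also fixed beforehand, because the files hold FPKM. Differences were tested with limma 3.58.1 (eBayes with trend) in R 4.3.3 on log2(FPKM + 1), in 1 fit of all 10 libraries with 1 coefficient per genotype, no covariate and 5 residual degrees of freedom, over the 19460 loci with a mean of at least 1 FPKM; p-values were Benjamini-Hochberg adjusted and called under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Simulated libraries tested the fit for atbmi1ab_strong against WT over 19460 loci. Of 50 genes each changed 1.5-, 2-, 4- and 8-fold, 32%, 80%, 98% and 98% were recovered, with 9 calls among unchanged loci. The changed genes were all above about 5 FPKM in WT and were few. These rates therefore do not carry over to lower loci or to a comparison with many changed loci.

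Before the data were examined, 17 gene lists with 280 genes (277 of them in the files), the 6 comparisons, the alternatives and the naming rule were fixed. The lists covered Polycomb components with associated factors, embryo and seed maturation regulators, seed storage and oil body genes, endosperm, pollen, floral identity, flowering time, meristem, root tissue, photosynthesis, stomatal lineage, trichome, auxin, anthocyanin, abscisic acid with cold and dehydration, defence and cell cycle genes. The 14 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry beside it. Since the filter used the mean over all 10 libraries, members low in every genotype were left out. A member silent in WT was tested only if a mutant raised it. Shares of tested members can therefore lean towards genes raised in a mutant. Named genes are AtBMI1A, AtBMI1B and AtBMI1C; the 5 highest and 5 lowest log2 fold changes per comparison among called loci with a symbol, a mean of at least 2 FPKM and no overlap between the libraries of the groups compared (this last not asked of the non-additivity contrast); and up to 3 called members per list with the smallest adjusted p. FUS3, ABI3 and the clock and heat-shock genes of the closing section were named after their values were seen. Overlaps of calls were set beside independent lists and beside 20 simulations of unchanged groups against shared WT libraries. The WT libraries were simulated as well.

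The alternatives were another scaling, other filters, a pseudocount of 0.1, the replicate block, a fit of the compared groups alone, removal of organelle genes and leaving out each library in turn. Added after the data were seen were quantile normalization, the single-mutant libraries as reference in place of WT, the fits of the other comparisons without atbmi1a replicate 1, the storage list without CRA1 and CRU3, overlaps with a separate WT library for each comparison, and the additive sum held at 0 in the non-additivity contrast. Figures were drawn with matplotlib in Python. Groups of 2 libraries are too small for a count over other splits of the samples.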

Results

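RNA was sequenced from 10 DAG (days after germination) seedlings of Arabidopsis thaliana, ecotype Col-0, of 5 genotypes with 2 libraries each. The genotypes were wild type (WT), the single mutants atbmi1a and atbmi1b, a double mutant of strong phenotype (atbmi1ab_strong) and a triple mutant (atbmi1abc). AtBMI1A, AtBMI1B and AtBMI1C are RING-finger proteins of Polycomb repressive complex 1 (PRC1), which keeps developmental genes silent through histone H2A ubiquitination. Each library gave an FPKM value for 27086 loci, of which 19460 had a mean of at least 1 FPKM over the 10 libraries and were tested. The FPKM values of a library summed to between 792416 and 990295, and 4846 to 5983 loci per library were listed at 0. Relative depth, read from the smallest step between low values, lay between 0.819 and 1.349 times that of WT replicate 1. Libraries of the same genotype correlated at 0.956 (atbmi1a) to 0.989 (atbmi1b) across the tested loci on the log2 scale. The highest correlation between libraries of different genotypes was 0.968, above that of the atbmi1a pair. The first principal component held 67% of the variance and set WT and the single mutants (-97.35 to -60.8) apart from the double and triple mutants (90.16 to 150.14).

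The targeted genes were read first, as a check of the labels. AtBMI1B (AT1G06770, TAIR10.1 chromosome 1, 2078880 to 2082097) fell from 6.10 ± 0.34 FPKM in WT to 0.145 ± 0.053 in atbmi1b and 1.80 ± 0.15 in atbmi1ab_strong, and to 3.77 ± 0.18 in atbmi1abc (SD, n = 2 each). AtBMI1A (AT2G30580, chromosome 2, 13025911 to 13030661) was higher, not lower, in the libraries labelled atbmi1a, at 30.1 ± 4.7 FPKM against 6.50 ± 0.58 in WT (log2 fold change 2.05 ± 0.16, SE; adjusted p = 0.000275). It stood at 8.54 ± 0.92 FPKM in the libraries labelled atbmi1ab_strong (0.35 ± 0.16, adjusted p = 0.0958) and rose to 12.0 ± 2.4 in those labelled atbmi1abc (0.79 ± 0.16, adjusted p = 0.00265). AtBMI1C (AT3G23060, chromosome 3, 8200636 to 8203335) was near the floor in WT, at 0.0906 ± 0.0636 FPKM, and rose to 3.32 ± 0.14 in atbmi1ab_strong and 3.69 ± 0.93 in the libraries labelled atbmi1abc. A value per locus does not tell which part of a transcript was read, and an interrupted gene can still give RNA, so these values neither clear nor exclude the labels of atbmi1a, atbmi1ab_strong and atbmi1abc. The directions given from here on are those of the libraries as labelled.

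**Figure D1:**
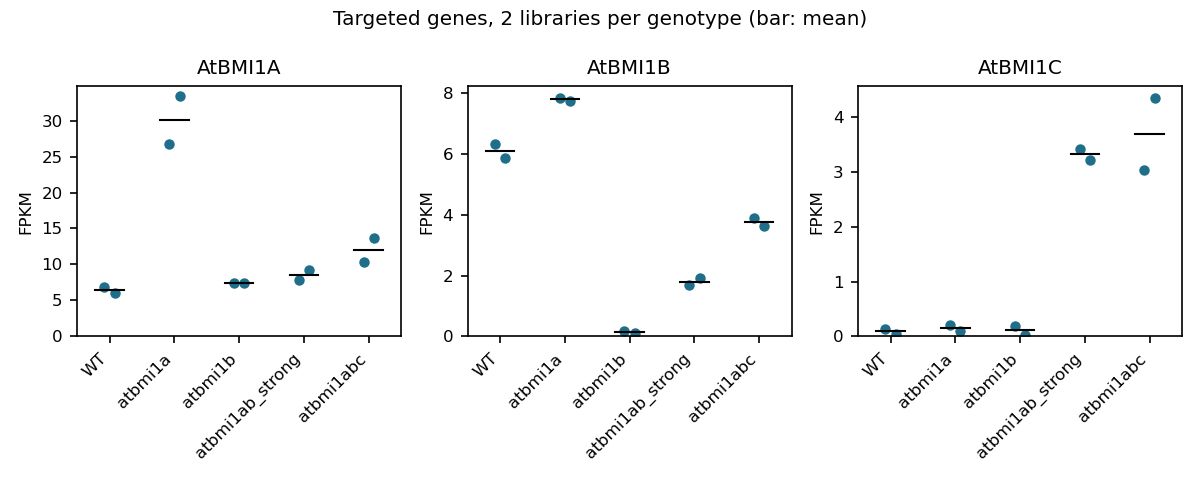
FPKM of AtBMI1A, AtBMI1B and AtBMI1C (vertical axes, linear, from 0) in each library of the 5 genotypes, with points for libraries and a bar for the mean of 2. AtBMI1A is highest in the libraries labelled atbmi1a (mean 30.1), AtBMI1B lowest in atbmi1b (0.145), and AtBMI1C is above 3 on average in the double and triple mutants.

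The first comparison took the libraries labelled atbmi1a against WT. HSP70, a cytosolic chaperone gene, went from 8.38 ± 2.14 FPKM to 384 ± 317 (SD, n = 2 each; log2 fold change 5.08 ± 0.52, SE), and the small heat-shock genes HSP17.4 and HSP17.6A rose by 5.08 ± 0.26 and 5.04 ± 0.33. HSP90.1 rose by 4.89 ± 0.54. The strongest decreases were in CCL, a CCR-like gene, from 926 ± 190 to 26.1 ± 10.08 FPKM (-5.13 ± 0.54), in the branched-chain amino acid transaminase gene BCAT-2 (-4.26 ± 0.26), in the cold-regulated gene COR413IM1 (-4.04 ± 0.20), in the auxin-response gene IAA29 (-3.90 ± 0.26) and in the senescence-associated gene SEN1 (-3.76 ± 0.33). DIC2, a mitochondrial carrier gene, had the highest fold change of the named genes (5.36 ± 1.22), and its call was lost without WT replicate 2 (adjusted p = 0.0731) or atbmi1a replicate 2 (0.0501). In all, 3299 loci rose and 3575 fell, of which 829 and 816 by more than 1 on the log2 scale (limma, Benjamini-Hochberg adjusted p under 0.05). Together the called loci were 35.3% of those tested.

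Among nuclear photosynthesis genes, 19 of 26 fell and 1 rose in the libraries labelled atbmi1a (20 and 1 adjusted over the list alone). The photosynthesis list had a camera adjusted p = 2.6e-05, and adjusted p = 0.683 with an estimated correlation. The light-harvesting genes LHCB1.4 and LHCB1.5 fell (-1.85 and -1.32), and the Rubisco small-subunit gene RBCS1B rose by 1.58 ± 0.18; members of both families are near-identical copies whose reads could be split between them. Anthocyanin and flavonoid genes rose in 6 of 7 cases (7 adjusted over the list alone), with F3H at 3.2 ± 0.27, chalcone synthase CHS at 2.23 ± 0.24 and CHI at 1.90 ± 0.22. The anthocyanin list had a camera adjusted p = 0.000174, and adjusted p = 0.585 with an estimated correlation. Of 8 defence markers 5 rose (5 adjusted over the list alone), among them PR5 at 1.09 ± 0.12, while PR1 was listed at 0 in both WT libraries and averaged 13.6 ± 12.6 FPKM. The defence list had a camera adjusted p = 0.00813, and adjusted p = 0.585 with an estimated correlation. Of 16 root markers 5 fell (5 adjusted over the list alone), and the auxin genes PIN7 and YUC8 fell (-1.83 and -2.12). The root list had a camera adjusted p = 0.0152, and adjusted p = 0.683 with an estimated correlation. That camera call was lost without atbmi1a replicate 2 (adjusted p = 0.0764), while without replicate 1 it held (0.00143) and 9 fell. Abscisic acid, cold and dehydration genes rose in 6 of 12 cases (6 adjusted over the list alone). The abscisic acid list had a camera adjusted p = 0.0233, and adjusted p = 0.585 with an estimated correlation. Its camera call was lost without WT replicate 1 (adjusted p = 0.0742) or atbmi1a replicate 2 (0.0764). Of 24 seed storage and oil body genes 1 was called, M17, a LEA-protein gene, at 0.75 ± 0.22 (0 adjusted over the list alone; its call was lost without either WT library, adjusted p = 0.0845 and 0.151, and without atbmi1a replicate 2, 0.148). The median of this list was 2.17 and came from 1 library: CRA1, a cruciferin gene, was at 588 FPKM in atbmi1a replicate 1 and 9.17 in replicate 2, and without replicate 1 the list median was -0.25. The storage list had a camera adjusted p = 0.0252, and adjusted p = 0.688 with an estimated correlation. Camera gave it an adjusted p = 0.31 without atbmi1a replicate 1 and 0.0677 without WT replicate 2. The counts of called loci dropped by more than 1.5 times to 1952 higher and 2373 lower without WT replicate 1, to 1725 and 2077 without WT replicate 2, and to 1366 and 1685 with only the 4 libraries compared.

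The second comparison took atbmi1b against WT. HSFA2, a heat-shock transcription factor gene, had the highest fold change of the named genes and went from 0.271 ± 0.212 FPKM to 81.2 ± 21.0 (SD, n = 2 each; log2 fold change 6.0 ± 0.71, SE), the early light-induced genes ELIP1 and ELIP2 rose by 5.94 ± 0.37 and 5.86 ± 0.35, and HSP70 rose by 5.6 ± 0.52. DIC2 rose by 5.42 ± 1.22, a call that was lost without WT replicate 2 (adjusted p = 0.0523) or atbmi1b replicate 1 (0.0514). CCL fell again (-6.59 ± 0.54), as did COR413IM1 (-5.71 ± 0.20), the asparagine synthetase gene ASN1 (-5.25 ± 0.35), the MYB repressor gene MYBL2 (-4.74 ± 0.37) and P1R3 (-4.42 ± 0.17). In all, 4148 loci rose and 4689 fell, 1512 and 1347 of them by more than 1 on the log2 scale.

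Nuclear photosynthesis genes fell in 21 of 26 cases in atbmi1b and rose in 1 (21 and 1 adjusted over the list alone); LHCB1.4 went from 4010 ± 1142 to 407 ± 17 FPKM (-3.27 ± 0.22) and LHCA4 fell as well (-1.73 ± 0.13). The photosynthesis list had a camera adjusted p = 4.44e-07, and adjusted p = 0.626 with an estimated correlation. All 7 tested anthocyanin and flavonoid genes rose (7 adjusted over the list alone), F3H by 4.46 ± 0.27, CHI by 3.05 ± 0.22 and CHS by 2.70 ± 0.24. The anthocyanin list had a camera adjusted p = 0.000195, and adjusted p = 0.626 with an estimated correlation. Of 8 defence markers 4 rose, with the camalexin synthesis gene PAD3 at 2.80 ± 0.18, and the list missed the threshold (camera adjusted p = 0.0547; 0.0434 without WT replicate 2 and 0.0271 without atbmi1b replicate 2). Of 16 root markers 7 fell (8 fell and 1 rose adjusted over the list alone), including LRX1 at -1.20 ± 0.26. Of 15 auxin genes 4 fell and 2 rose, with PIN7 at -2.33 ± 0.10 and PIN5 at 1.56 ± 0.22. Neither list passed camera (adjusted p = 0.0972 for root and 0.649 for auxin). Their called shares lay close to the 45.4% of all tested loci. The flowering-time genes SPL3 and SMZ moved apart, at -2.26 ± 0.23 and 1.87 ± 0.20, and the trichome regulator GL2 fell (-1.33 ± 0.11).

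The single mutants were then set side by side. Of the loci called in each, 2646 were higher in both and 3113 lower in both, and 19 went opposite ways; independent lists of these sizes would share 703.2 and 861.4. CCL, COR413IM1, PIN7, HSP70 and F3H were among the genes that moved the same way in both. Across the tested loci the log2 fold changes correlated at 0.873, against 0.498 for unchanged groups set against shared WT libraries, all of them simulated. The covariance was 0.561 against a simulated 0.0262. The 20 simulations shared on average 0 calls. They held no changed locus, so a count near 0 was fixed in advance and does not bear on the overlap. With a separate WT library for each comparison, 1330 or 1451 loci were higher in both and 1696 or 1934 lower, depending on which library went with which, and the correlation was 0.776 or 0.794. Independent lists of those sizes would share 275 or 300.2 higher and 386.6 or 410.3 lower. No WT library entered both comparisons in this check, so chance values of a shared WT library cannot give its correlation. A shift common to both WT libraries would still enter both comparisons.

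The third comparison took the libraries labelled atbmi1ab_strong against WT. Seed storage genes rose most: the cruciferin gene CRU2 went from 3.02 ± 0.02 FPKM to 9880 ± 1377 (SD, n = 2 each; log2 fold change 11.26 ± 1.33, SE), the albumin genes SESA3, SESA1 and SESA2 rose by 11.12 ± 1.5, 10.92 ± 1.17 and 10.85 ± 1.51, and the oleosin gene OLEO1 went from 7.13 ± 1.16 to 14800 ± 1970 FPKM. Their standard errors were wide, since atbmi1a replicate 1, which enters the pooled spread, also carried these transcripts. Photosynthesis genes fell most: LHCB1.4 went from 4010 ± 1142 to 4.13 ± 0.97 FPKM (-9.60 ± 0.22), the Rubisco gene RBCS2B from 2960 ± 178 to 7.76 ± 0.80 (-8.40 ± 0.14), and the carbonic anhydrase genes CA1 and CA2 fell as well (-8.0 ± 0.20 and -8.14 ± 0.40). CCL fell too (-8.10 ± 0.54). In all, 6193 loci rose and 6341 fell, 3353 and 2955 of them by more than 1 on the log2 scale. Together the called loci were 64.4% of those tested.

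Of 20 embryo and seed maturation regulators 15 were tested, and 13 of these rose in the libraries labelled atbmi1ab_strong (13 adjusted over the list alone). The embryo regulator list had a camera adjusted p = 1.39e-05, and adjusted p = 0.411 with an estimated correlation. FUS3 and ABI3, B3-domain regulators of seed maturation, rose from 0.152 ± 0.042 and 0.0391 ± 0.0182 FPKM to 55.6 ± 1.0 and 50.9 ± 5.5. AIL5, AGL15 and WRI1 rose by 4.96 ± 0.28, 2.86 ± 0.16 and 3.28 ± 0.20. Seed storage and oil body genes rose in 20 of 24 cases and 1, M17, fell (21 and 3 adjusted over the list alone), with a list median of 9.29. The storage list had a camera adjusted p = 4.83e-05, and adjusted p = 0.525 with an estimated correlation. CRA1 and CRU3 were among the genes not called: both were listed at 0 in both atbmi1ab_strong libraries, against 12.97 ± 0.83 and 12.7 ± 2.1 FPKM in WT, so no fold is given, and without them the list median was 9.33. All 26 photosynthesis genes fell (26 adjusted over the list alone). The photosynthesis list had a camera adjusted p = 8.51e-18, and adjusted p = 0.279 with an estimated correlation, and its median was -5.38.

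Of 9 stomatal lineage genes 8 fell and 1 rose in the libraries labelled atbmi1ab_strong (8 and 1 adjusted over the list alone), with the guard-cell regulator FAMA at -3.36 ± 0.16 and STOMAGEN at -2.62 ± 0.14. The stomatal list had a camera adjusted p = 0.00512, and adjusted p = 0.171 with an estimated correlation. Meristem and stem cell regulators rose in 12 and fell in 3 of 19 cases (12 and 3 adjusted over the list alone), with AIL6 at 3.11 ± 0.15, the root stem cell gene WOX5 at 4.14 ± 0.32 and PRS at 2.23 ± 0.17. The meristem list had a camera adjusted p = 0.0107, and adjusted p = 0.522 with an estimated correlation. Abscisic acid, cold and dehydration genes rose in 11 of 12 cases and 1 fell (11 and 1 adjusted over the list alone), LTI30 from 19.8 ± 1.4 to 858 ± 130 FPKM and RD29A by 5.90 ± 0.30. The abscisic acid list had a camera adjusted p = 0.000533, and adjusted p = 0.171 with an estimated correlation. Anthocyanin genes rose in 6 of 7 cases (7 adjusted over the list alone). The anthocyanin list had a camera adjusted p = 0.00318, and adjusted p = 0.522 with an estimated correlation. This call was lost with the single-mutant libraries as reference (adjusted p = 0.577), where 4 rose and 2 fell and the median was 0.61 against 3.07. Among flowering-time genes 5 rose and 8 fell of 17: the floral repressor genes MAF5 and MAF4 rose by 3.67 ± 0.17 and 2.50 ± 0.12, and SVP fell (-4.08 ± 0.21). Of 16 root markers 5 rose, PIN2 by 2.0 ± 0.23 (camera adjusted p = 0.151). With the single-mutant libraries as reference 14 rose, the median was 0.80 against 0.13 and the list was called (adjusted p = 0.00195). Of 15 auxin genes 7 fell and 3 rose, with PIN4 at -2.93 ± 0.14.

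**Figure D2:**
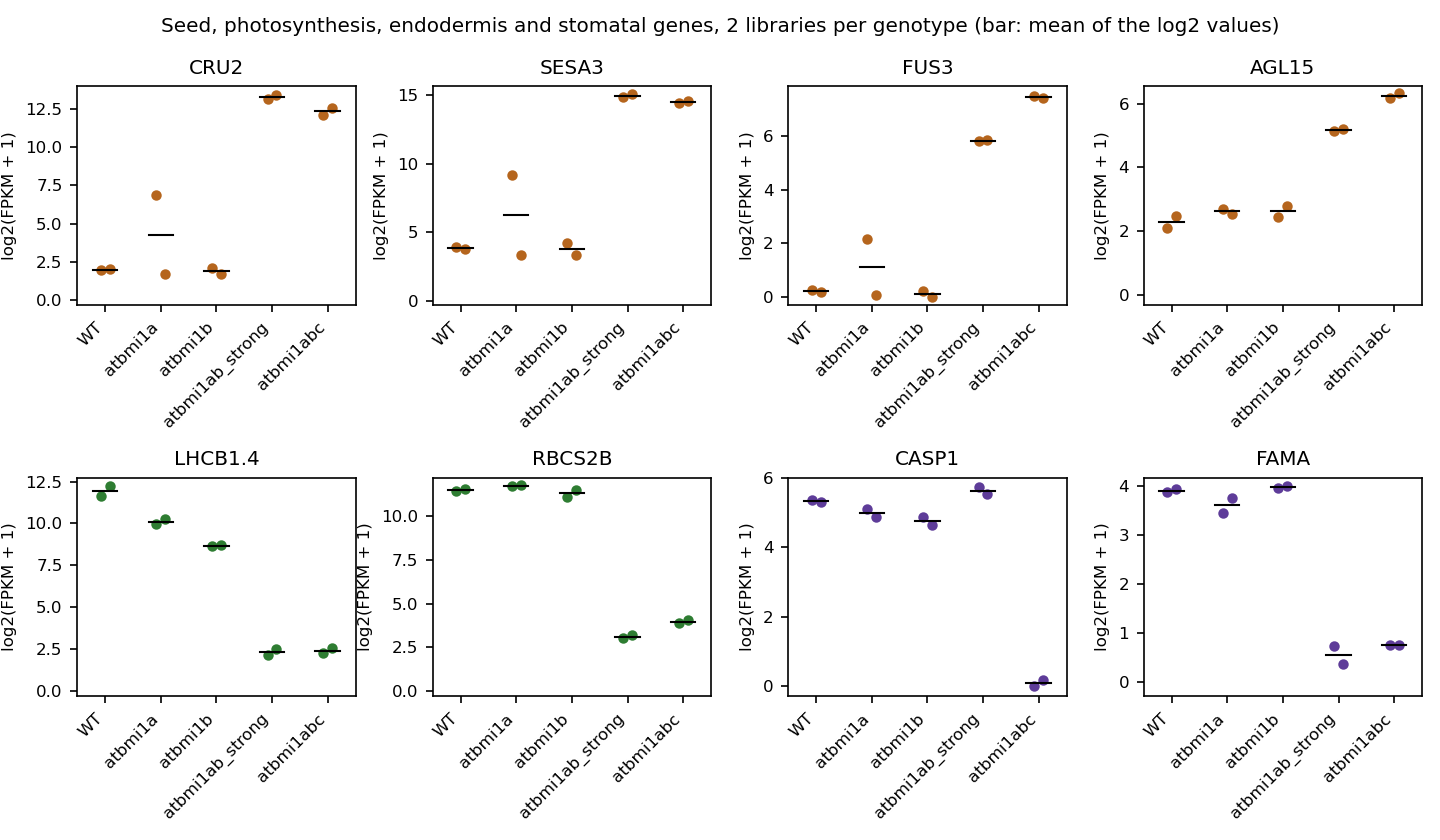
Levels as log2(FPKM + 1) (vertical axes) of 8 genes in each library of the 5 genotypes, with points for libraries and a bar for the mean of the 2 log2 values. CRU2, SESA3, FUS3 and AGL15 are higher and LHCB1.4, RBCS2B and FAMA lower than WT in the double and triple mutants, CASP1 is near 0 in atbmi1abc, and atbmi1a replicate 1 lies apart from replicate 2 for CRU2 and SESA3.

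The fourth comparison took the libraries labelled atbmi1abc against WT. Seed storage genes were again at the top: CRA1 rose from 12.97 ± 0.83 to 25380 ± 4244 FPKM (SD, n = 2 each; log2 fold change 10.82 ± 1.51, SE), and SESA2, SESA4, SESA3 and OLEO1 rose by 10.70 ± 1.51, 10.67 ± 1.55, 10.66 ± 1.5 and 10.65 ± 1.56. SEN1 fell from 1879 ± 282 to 0.821 ± 0.103 FPKM (-10.01 ± 0.33), and LHCB1.4 (-9.51 ± 0.22), the drought-repressed gene DR4 (-9.47 ± 0.18) and the major latex protein gene MLP34 (-8.65 ± 0.22) fell as well. MLP328, another of that family, was at 406 ± 27 FPKM in WT and listed at 0 in both atbmi1abc libraries. In all, 7067 loci rose and 7343 fell, 3713 and 4574 of them by more than 1 on the log2 scale.

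Of 20 embryo and seed maturation regulators 15 were tested, and all 15 rose in the libraries labelled atbmi1abc (15 adjusted over the list alone). Members at 0 in WT, such as ABI4 and WOX8, passed the filter only through their mutant levels, so this count was partly fixed in advance. The embryo regulator list had a camera adjusted p = 5.38e-07, and adjusted p = 0.3 with an estimated correlation. FUS3 reached 174 ± 6 FPKM, AGL15 rose by 3.95 ± 0.16, and ABI4 and WOX8, listed at 0 in both WT libraries, averaged 17.43 ± 3.61 and 16.5 ± 1.8 FPKM. Of 24 seed storage and oil body genes 23 rose (23 adjusted over the list alone). The storage list had a camera adjusted p = 7.69e-06, and adjusted p = 0.354 with an estimated correlation, and its median was 9.76. All 26 photosynthesis genes fell (26 adjusted over the list alone), including RBCS3B (-7.63 ± 0.10) and LHCB2.2 (-6.41 ± 0.12). The photosynthesis list had a camera adjusted p = 6.43e-14, and adjusted p = 0.3 with an estimated correlation. Of 16 root markers 13 fell and 1 rose (13 and 1 adjusted over the list alone): the endodermal Casparian strip genes CASP1 and CASP2 fell (-5.25 ± 0.13 and -4.07 ± 0.14). The root list had a camera adjusted p = 0.000754, and adjusted p = 0.328 with an estimated correlation. Stomatal genes fell in 8 of 9 cases and 1 rose (8 and 1 adjusted over the list alone), with FAMA at -3.15 ± 0.16; the riser, ICE1, a transcription factor gene also known from the cold response, went from 42.7 ± 2.3 to 336 ± 12 FPKM. The stomatal list had a camera adjusted p = 0.0288, and adjusted p = 0.3 with an estimated correlation.

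Polycomb components and associated factors rose in 15 and fell in 4 of 23 cases in the libraries labelled atbmi1abc (15 and 4 adjusted over the list alone), with the PRC1 gene RING1B at 2.05 ± 0.10, the B3-domain gene VAL1 at 2.33 ± 0.12 and ULT1 at 2.53 ± 0.14. The Polycomb list had a camera adjusted p = 0.0139, and adjusted p = 0.3 with an estimated correlation. It also holds ULT1, ATX1, REF6, ELF6 and PKL, which are not Polycomb components, and the targeted genes AtBMI1A, AtBMI1B and AtBMI1C themselves. Meristem regulators rose in 14 and fell in 3 of 19 cases (14 and 3 adjusted over the list alone), with the boundary gene CUC1 at 3.63 ± 0.16 and SCR at 2.04 ± 0.11. The meristem list had a camera adjusted p = 0.00289, and adjusted p = 0.354 with an estimated correlation. Anthocyanin genes rose in 6 of 7 cases (6 adjusted over the list alone). The anthocyanin list had a camera adjusted p = 0.00662, and adjusted p = 0.354 with an estimated correlation. With the single-mutant libraries as reference it was not called (adjusted p = 0.507), 4 rose and 3 fell, and the median was 1.37 against 3.83. The other lists did not pass camera or held too few tested members. The called shares of the auxin, cell cycle and trichome lists lay close to the 74% of all tested loci. Flowering-time genes rose in 4 and fell in 13 of 17 cases (SVP -5.21 ± 0.21, MAF4 2.72 ± 0.12), auxin genes rose in 4 and fell in 7 of 15 (PIN3 -3.63 ± 0.19), and abscisic acid, cold and dehydration genes rose in 7 and fell in 3 of 12 (RD29A 3.59 ± 0.30, COR47 -3.64 ± 0.18). Defence markers fell in 4 of 8 cases (3 adjusted over the list alone; camera adjusted p = 0.252). With the single-mutant libraries as reference all 8 fell, the median was -1.70 against -0.66 and the list was called (adjusted p = 0.0129). Cell cycle genes rose in 5 and fell in 3 of 10 (CDKB1;1 1.54 ± 0.16), and trichome genes rose in 2 and fell in 3 of 7. With that reference 3 rose and 3 fell of the former and 3 and 2 of the latter, and of the abscisic acid list 6 rose and 5 fell (median 0.70 against 1.39). Of 3 tested floral identity genes SEP2 rose (3.28 ± 0.14) and SEP3 and SEP4 fell, of 4 tested pollen genes 2 fell, and the single tested endosperm and female gametophyte gene, AGL80, rose by 2.83 ± 0.22.

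The double and triple mutants were set side by side against WT. Both were higher at 4596 loci and both lower at 5019, and 785 loci went opposite ways; independent lists of these sizes would share 2249 and 2392.7. SESA3, OLEO1, LHCB1.4 and SVP were among the genes that moved the same way in both. The log2 fold changes correlated at 0.79 across loci, against 0.499 in the simulations, with a covariance of 2.3 against a simulated 0.0266. The simulations shared on average 0 calls, which was again fixed in advance because they held no changed locus. With a separate WT library for each comparison, 3758 or 3877 loci were higher in both and 4300 or 4344 lower, and the correlation was 0.762 or 0.779. Independent lists of those sizes would share 1691.7 or 1741.6 higher and 1878.3 or 1896 lower. Here too no WT library entered both comparisons, so chance values of a shared WT library cannot give this correlation. A shift common to both WT libraries would still enter both comparisons.

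The fifth comparison took the libraries labelled atbmi1abc against those labelled atbmi1ab_strong, and AtBMI1C, the gene that the labels add, was not called between them (0.11 ± 0.18, adjusted p = 0.636). AtBMI1B rose (0.77 ± 0.12), and the call of AtBMI1A (0.44 ± 0.16, adjusted p = 0.0493) was lost without either atbmi1ab_strong library (0.215 and 0.0708) or atbmi1abc replicate 2 (0.272). BNQ3, a small helix-loop-helix protein gene, rose from 1.303 ± 1.842 to 102 ± 13 FPKM (SD, n = 2 each; log2 fold change 5.76 ± 0.57, SE), the B-box zinc finger gene BBX10 by 4.96 ± 0.33 and the methylcytosine-binding family gene VIM5 by 3.86 ± 0.40. CRA1 and CRU3, listed at 0 in both atbmi1ab_strong libraries, averaged 25380 ± 4244 and 21380 ± 5539 FPKM in atbmi1abc. The glycine-rich protein gene GRP9 fell from 804 ± 35 to 0.799 ± 0.099 FPKM (-8.81 ± 0.10), and DR4 (-8.21 ± 0.18), MLP34 (-7.21 ± 0.22) and DOT1 (-7.16 ± 0.18) fell as well. MLP328 stood at 151 ± 3 FPKM in atbmi1ab_strong and was listed at 0 in atbmi1abc. In all, 6256 loci rose and 4904 fell, 1005 and 3045 of them by more than 1 on the log2 scale. Together the called loci were 57.3% of those tested. The balance depends on scaling: quantile normalization, added after the data were seen, gave 7801 and 4113, with a median log2 fold change of 0.22 against 0.10 as deposited.

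Among the lists tested, root markers had the smallest camera adjusted p at the preset correlation in this comparison, though not with an estimated one. Their median was -2.50, against -2.48 for the abscisic acid list. Of 16 root markers 14 fell and 1 rose in the libraries labelled atbmi1abc (14 and 1 adjusted over the list alone). CASP1 went from 48.7 ± 4.6 to 0.0656 ± 0.0927 FPKM and CASP2 fell by -4.19 ± 0.14. The root list had a camera adjusted p = 3.18e-07, and adjusted p = 0.166 with an estimated correlation. Embryo and seed maturation regulators rose in 10 and fell in 1 of 15 cases (10 and 1 adjusted over the list alone), with WOX2 at 3.67 ± 0.25, WOX9 at 2.86 ± 0.19 and WOX8 at 2.51 ± 0.16. The embryo regulator list had a camera adjusted p = 0.00312, and adjusted p = 0.454 with an estimated correlation. Of 24 seed storage genes 3 rose and 21 did not pass, CRA1 and CRU3 being 2 of the 3, and the list median was 0.02. Without atbmi1a replicate 1, 4 rose and 5 fell. Polycomb components and associated factors rose in 14 of 23 cases (14 adjusted over the list alone). Among them were the PRC2 gene FIE at 0.82 ± 0.09, the PRC1 gene RING1A at 1.03 ± 0.14 and ULT1, not itself a Polycomb component, at 1.33 ± 0.14. The Polycomb list had a camera adjusted p = 0.00312, and adjusted p = 0.158 with an estimated correlation. Abscisic acid, cold and dehydration genes fell in 7 of 12 cases and 1 rose (7 and 1 adjusted over the list alone), including COR47 (-5.67 ± 0.18) and RD26 (-3.25 ± 0.18). The abscisic acid list had a camera adjusted p = 0.00384, and adjusted p = 0.158 with an estimated correlation. Of 8 defence markers 6 fell (6 adjusted over the list alone), among them SID2 at -1.55 ± 0.21. The defence list had a camera adjusted p = 0.0138, and adjusted p = 0.447 with an estimated correlation. Flowering-time genes fell in 7 of 17 cases (6 adjusted over the list alone), among them SMZ (-2.08 ± 0.20). The flowering-time list had a camera adjusted p = 0.0197, and adjusted p = 0.372 with an estimated correlation. This camera call was lost without atbmi1ab_strong replicate 2 (adjusted p = 0.0527).

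The last comparison asked whether the double mutant equals the sum of the single mutants on the log2 scale; a positive value means that atbmi1ab_strong lies above that sum. COR413IM1 lay at 9.33 ± 0.28 (SE): it stood at 101 ± 13 FPKM in WT, 5.23 ± 0.95 in atbmi1a, 0.958 ± 0.411 in atbmi1b and 75.4 ± 9.2 in atbmi1ab_strong (SD, n = 2 each). Its sum falls at -3.08, below the floor of the log2(FPKM + 1) scale, and with the sum held at 0 the value was 6.25. The storage genes CRU2, SESA1 and SESA3 lay at 9.06 ± 1.88, 9.01 ± 1.65 and 8.75 ± 2.12, with the glyoxylate cycle gene ICL at 8.76 ± 1.76. RBCS1B had the lowest value (-9.33 ± 0.25), rising from 694 ± 117 FPKM in WT to 2061 ± 149 and 2888 ± 309 in the single mutants and standing at 12.3 ± 0.3 in the double mutant, and CA1, SQP1, CA2 and CP12-2 lay between -9.16 and -8.49. In all, 6338 loci lay above the sum and 5509 below it, and for 206 of the former the sum was under that floor. Together the called loci were 60.9% of those tested.

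All 26 photosynthesis genes lay below the sum (26 adjusted over the list alone). The photosynthesis list had a camera adjusted p = 8.55e-16, and adjusted p = 0.346 with an estimated correlation. Of 9 stomatal genes 7 lay below it and 1 above (7 and 1 adjusted over the list alone). The stomatal list had a camera adjusted p = 0.0043, and adjusted p = 0.303 with an estimated correlation. Of 7 anthocyanin genes 6 lay below and 1 above (6 and 1 adjusted over the list alone). The anthocyanin list had a camera adjusted p = 0.0389, and adjusted p = 0.551 with an estimated correlation. Embryo regulators lay above the sum in 12 of 15 cases and below in 1 (12 and 1 adjusted over the list alone). The embryo regulator list had a camera adjusted p = 0.00164, and adjusted p = 0.485 with an estimated correlation. Seed storage genes lay above it in 21 of 24 cases and below in 3 (21 and 3 adjusted over the list alone), the 3 being M17 and the genes listed at 0 in the double mutant, CRA1 and CRU3. The storage list had a camera adjusted p = 0.00369, and adjusted p = 0.552 with an estimated correlation. Root markers lay above it in 14 of 16 cases (14 adjusted over the list alone). The root list had a camera adjusted p = 0.00166, and adjusted p = 0.446 with an estimated correlation.

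Defence markers lay below the sum in 5 of 8 cases and above in 1 (5 and 1 adjusted over the list alone). The defence list had a camera adjusted p = 0.042, and adjusted p = 0.485 with an estimated correlation. Abscisic acid, cold and dehydration genes lay above it in 8 of 12 cases and below in 1 (8 and 1 adjusted over the list alone). The abscisic acid list had a camera adjusted p = 0.042, and adjusted p = 0.346 with an estimated correlation. These last 2 calls were lost without some single libraries: the first without atbmi1b replicate 1 (adjusted p = 0.0646) or atbmi1ab_strong replicate 2 (0.0917), the second without WT replicate 2 (0.0657), atbmi1a replicate 1 (0.0662) or atbmi1b replicate 1 (0.051). WT enters this contrast with the opposite sign to its place in the single-mutant comparisons, so any shift of WT alone appears in it as well. The contrast also takes the double mutant to carry the alleles of the single mutants, which the levels of AtBMI1A and AtBMI1B did not show.

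**Figure D3:**
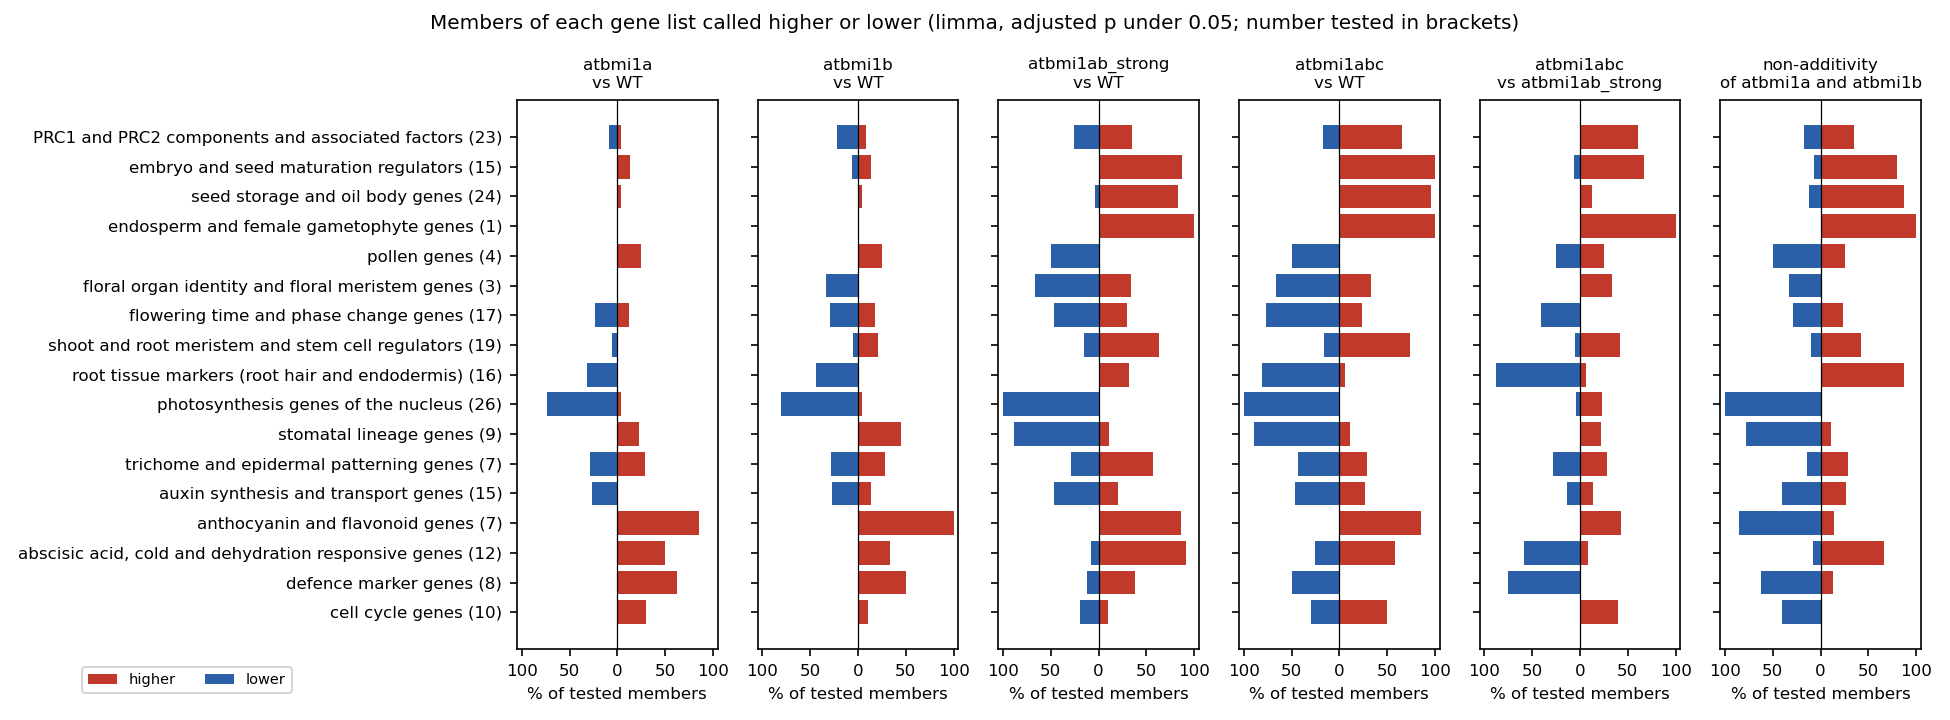
For each gene list (rows, number of tested members in brackets) and each of the 6 comparisons (panels), the percent of tested members called higher (red, to the right) or lower (blue, to the left) by limma at an adjusted p under 0.05. Photosynthesis genes reach 100% lower in atbmi1ab_strong and atbmi1abc, embryo regulators 100% higher in atbmi1abc, and root markers are mostly lower in atbmi1abc against atbmi1ab_strong.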

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

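The non-additivity contrast tests whether atbmi1ab_strong differs from the sum of the single mutants on the log2 scale. Its called results are given here because that test showed a difference between genotypes (limma, adjusted p under 0.05). The contrast reads as an effect of 1 mutation that depends on the other only if the double mutant carries the alleles of the single mutants. The levels of AtBMI1A and AtBMI1B did not show this. The contrast called 6338 loci above the sum of the single mutants and 5509 below it. Of the targeted genes, AtBMI1A lay at -1.87, AtBMI1B at 0.98 and AtBMI1C at 1.88 on the log2 scale. The highest named genes were COR413IM1 at 9.33 (6.25 with the additive sum held at the floor of the scale), CRU2 at 9.06, SESA1 at 9.01, ICL at 8.76 and SESA3 at 8.75, and the lowest were RBCS1B at -9.33, CA1 at -9.16, SQP1 at -9.01, CA2 at -8.87 and CP12-2 at -8.49. The camera calls used the preset correlation, and with an estimated one none of the 8 lists was called (smallest adjusted p = 0.303). Those lists had medians of 7.45 for seed storage and oil body genes, 2.41 for embryo and seed maturation regulators, 1.77 for abscisic acid, cold and dehydration genes, 1.34 for root tissue markers, -1.85 for anthocyanin and flavonoid genes, -1.86 for defence markers, -2.47 for stomatal lineage genes and -3.66 for photosynthesis genes. Without atbmi1a replicate 1, in which seed transcripts were raised, the median of the seed storage list was 9.68. The patterns that bear on these values are weighed among the other observations.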

How the results depend on the processing

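Quantile normalization, the single-mutant reference and the fits without atbmi1a replicate 1 outside its own comparisons were chosen after the data were seen, and the DESeq2 alternatives were not run, because the files hold no counts. Of the counts, 207 alternatives were labelled the same and 15 moved. The same does not mean equal here, since smaller changes of a count keep that label. With quantile normalization the 6256 higher loci of atbmi1abc against atbmi1ab_strong became 7801 and were labelled the same. For the named genes, 4412 results were labelled the same, 151 weaker, 1 stronger and 9 reversed. These are not numbers of genes, since a gene counts once for each comparison and each alternative. For a named gene the label rests on its sign and its call, not on the size of its fold change. For atbmi1a against WT, the 3299 higher and 3575 lower loci became 1366 and 1685 with only the libraries compared, and ranged from 1725 to 3250 and from 2077 to 3364 when 1 library was left out. With an estimated correlation the called lists went to 0 for atbmi1a, atbmi1b, atbmi1ab_strong and atbmi1abc against WT, for atbmi1abc against atbmi1ab_strong and for non-additivity. In the same order fry called 6, 7, 9, 12, 8 and 12 lists, those of atbmi1b going from 2 to 7. Fry asks whether list members change at all, and camera whether they change more than other loci. With 35.3% to 74% of all tested loci called, a fry call does not check a camera call. The abscisic acid list had an estimated correlation of 0.011, near the preset 0.01. Its camera adjusted p in atbmi1ab_strong still went from 0.000533 to 0.171, so a higher correlation does not account for that loss. The stomatal list, with an estimated correlation of -0.059, went from 0.00512 to 0.171 there. The drop to 0 called lists therefore does not measure correlation alone. With an absolute log2 fold change of at least 1 the overlap was 4743 for the double and triple mutants and 1363 for the single mutants. AtBMI1C, near the floor, turned to -0.14 in atbmi1a and -0.064 in atbmi1b with quantile normalization, ranged from -0.076 to 0.13 in atbmi1b (-0.034 without WT replicate 2) and from -0.10 to 0.31 in atbmi1abc against atbmi1ab_strong when 1 library was left out. Against the single-mutant libraries, AtBMI1A turned to -0.76 and PAD3 to -0.89 in atbmi1ab_strong, and AtBMI1A to -0.32 and AtBMI1B to 0.59 in atbmi1abc, while 72.5% and 80.4% of the calls against WT were called again in the same direction and 573 and 398 loci in the opposite one. With the replicate block the counts were 3128 and 3408 for atbmi1a, and the numbers do not pair the libraries (0 of 10 lay closest to their own number). The cause was not tested.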

Other observations

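The gene groups and the tests in this part were chosen after the data were seen, except the fixed seed lists. Most tested heat-shock genes rose in every mutant against WT: of 10 tested, 9 rose in the libraries labelled atbmi1a, 8 in atbmi1b, and 7 in each of those labelled atbmi1ab_strong and atbmi1abc, where 1 fell (limma, adjusted p under 0.05). The list had 12 members. HSP21 and HSP22.0 were too low to be tested, with means of at most 0.389 and 0.235 FPKM in any genotype. HSP101, a chaperone gene needed for heat tolerance, went from 3.58 ± 0.11 FPKM in WT to 43.4 ± 40.7, 88.6 ± 16.6, 36.3 ± 4.4 and 45.1 ± 17.7 (SD, n = 2 each), rising by 2.88 and 4.28 on the log2 scale in the single mutants. List medians were 4.48, 4.18, 2.50 and 2.40.

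Circadian clock genes moved apart. The morning genes CCA1 and LHY rose from 54.0 ± 1.6 and 54.6 ± 1.5 FPKM in WT to 143 ± 8 and 159 ± 20 in the libraries labelled atbmi1a and to 243 ± 32 and 326 ± 44 in atbmi1b, and fell to 8.73 ± 0.16 and 25.9 ± 0.7 in those labelled atbmi1ab_strong. PRR7 fell from 68.3 ± 2.0 to 24.7 ± 1.9, 13.8 ± 1.1 and 23.3 ± 4.0. Of 12 clock genes 3 rose and 4 fell in atbmi1a, and 4 rose and 3 fell in atbmi1b.

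Seed transcripts were raised in atbmi1a replicate 1 and not in replicate 2. Over 122 loci at least 100-fold above WT and atbmi1b in atbmi1abc, replicate 2 differed from WT by a median of -0.07 on the log2 scale (quartiles -0.25 and 0.12) against 2.91 in replicate 1, which argues against an effect of the genotype in both libraries. The excess in replicate 1 was a median of 2.75% of the atbmi1abc level over 99 loci outside the seed lists (quartiles 2.4 and 3.11) and 2.59% over the 23 inside, as RNA or reads of an atbmi1abc kind of library mixed into this one would give. Set against atbmi1ab_strong, the excess was 15.49% over the 10 loci at least 4-fold higher in atbmi1abc and 3.78% over 110 others, which argues against a source like atbmi1ab_strong. A few seedlings with an embryo-like programme in that sample could give the same proportions and were not tested apart.

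CRA1 and CRU3 were listed at 0 in both atbmi1ab_strong libraries, although 20 of the 22 other tested storage genes rose there. No other locus was at 0 in both libraries of WT, atbmi1a, atbmi1b or atbmi1ab_strong with at least 5 FPKM in all the others; atbmi1abc had 23 such loci. A failed estimate written as 0 would leave zeros at other high loci. AT2G01021, at 34183 FPKM in WT replicate 2, was at 0 to the nearest whole FPKM in atbmi1b replicate 1 and atbmi1abc replicate 2. The other library of each of these genotypes held 2492 and 7574 FPKM, so these zeros did not follow genotype, unlike those of CRA1 and CRU3. The shares below rest on few high loci, so the test could miss a difference. Apart from CRA1 and CRU3, 4.26% of the 47 loci that reach 3000 FPKM have a 0 in some library, against 2.56% of the 117 between 1000 and 3000 and 3.14% of the 2519 between 100 and 1000, and Fisher's exact test does not separate the first of these shares from the last (two-sided p = 0.659). Absence of both transcripts would sit beside 1 other storage gene, M17, that fell. These explanations cannot be told apart, since the reads behind the values were not analysed here.

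The single mutants share a large difference from WT. A different hour, light or temperature at harvest would move clock genes, and the clock list had a median absolute log2 fold change of 0.661 in atbmi1a and 0.765 in atbmi1b. These genes were picked after their values were seen, so the value describes them and does not test the harvest. A like effect of losing either protein would keep its direction in the double mutant: the 5759 loci called the same way in both stood in atbmi1ab_strong at a median of 0.515 (quartiles 0.032 and 1.279), 3418 of them called that way and 803 the other way. Both stay open and cannot be told apart, since no label gives harvest times and WT is shared by all the comparisons. The WT libraries also stood apart in chloroplast-encoded loci, at 0.744% and 2.24% of the FPKM sum against at most 0.24% in the others. Another difference of the WT libraries themselves was not tested and stays open too.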
